A study of Mus musculus with 2 samples.

How the data were processed

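The series holds droplet single-cell RNA sequencing of mouse tumours, with 1 library from the control group and 1 from the motolimod group. Per the labels' protocols, tumours of 5 mice per group were digested with collagenase D and DNase I, passed through a 70 µm strainer and enriched for CD45-positive immune cells on magnetic beads, to more than 95% purity and more than 85% viability. About 30000 cells per sample were loaded for a 3′ library. The labels do not state whether the mice of a group were pooled, and they name neither the tumour model nor the dose.

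The deposited values are raw UMI counts per gene and barcode, with no normalization, per the file headers. The reads were processed with Cell Ranger and the mm10 build, named as version 5.0.1 per the submitters' processing notes and as 7.1.0 per the file headers. The barcodes are those that its cell calling kept, and the setting for intron reads is not stated. Each deposited table of counts lists 32285 genes. The control library held 127609378 UMIs over 8099 barcodes and the motolimod library 62057685 UMIs over 10037 barcodes. Gene positions came from the GENCODE annotation of the same build. A symbol carried by more than 1 gene identifier (38 symbols) was kept apart by identifier. Such symbols were not used in gene lists, so Aldoa and Ccl19 (2 identifiers each) count as not measured, as do Cxcl11, Mx1 and Mx2, which no symbol matches.

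Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9, with the random seed fixed at 1. Barcodes passed with at least 300 genes, at least 800 UMIs and at most 10% mitochondrial UMIs, which left 7484 control (92.4%) and 9314 motolimod barcodes (92.8%). Scrublet, run per library in scanpy with an expected rate of 8.0%, called 0 doublets in each library with its automatic threshold and so had not worked. In its place, and unlike the design fixed before the data were examined, the barcodes with the highest Scrublet scores were removed at a rate of 0.8% per 1000 barcodes (448 control and 694 motolimod). Droplets with core genes of at least 2 of 5 lineages (T, macrophage, neutrophil, epithelial and B cells) were also removed, 842 (11.3%) and 820 (8.80%). Together 1065 (14.2%) and 1188 (12.8%) barcodes were removed, and 6419 and 8126 cells were kept, with median UMIs of 13155 and 3343.

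Kept cells of both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were used, and a graph of 15 neighbours was divided by the Leiden method at a resolution of 1.0. Clusters were named from 26 marker sets fixed before the data were examined. The naming rule was set after seeing the data, since an earlier version, which scored markers against the mean of all cells, was tried first. Under the rule used, a class was considered for a cluster if at least 3 of its markers reached 50 CPM. Its score was the mean log2 ratio of its markers to the 25th percentile over clusters, with 10 CPM added, and had to reach 1.0. A cluster stayed unnamed if its 10 leading genes, among genes of at least 100 CPM, held more markers of another class than of its own. Monocytes and macrophages formed a single class, scored by the better of their marker sets. T and NK cells, and dendritic cells, were clustered again with the same settings, and subclusters led by genes of other lineages were set aside. The epithelial cell class could hold tumour cells, which no marker fixed here tells apart.

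With 1 library per group there is no test, and no p-value is given. Shares of cells have exact Clopper-Pearson 95% intervals and ratios of shares and of counts have exact conditional binomial intervals. CPM of UMIs summed over the cells of a class and library have exact Poisson intervals. All of these cover counting error only. Genes were compared in classes and clusters with at least 100 kept cells in each library. The exceptions are the genes of the platelet factor 4 axis, Tlr7 and Tlr8, which were also given with fewer cells, such as in cluster 15 with 85 motolimod cells. A gene at 0 UMIs in a library was set to a floor of 3 counts for a bound. To compare shares of cells with a UMI, each cell was thinned to 1000 UMIs, and shallower cells, 91 control and 301 motolimod over all classes, were left out. Chosen after the data were seen, the Pf4 ratio was also computed with the control library's share of UMIs in each cluster, or in each of 10 bins of UMIs per cell with equal numbers of cells, with intervals from 2000 Poisson draws of the counts.

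The genes named in the text follow a rule fixed before the data were examined. It takes the genes of the platelet factor 4 axis and the 8 highest and 8 lowest ratios in each of 3 main classes. It also takes the 3 highest and 3 lowest in every other compared class. Up to 4 members of each fixed list with the largest log2 ratios are added. The rule names classes only. Its use for clusters and for CD8 T cell-like cells, and the gene lists compared in them, were not part of the fixed design. Genes had to reach 50 CPM and 100 UMIs in the higher library. Mitochondrial and ribosomal protein genes, unnamed gene models, haemoglobin genes, variable immunoglobulin and T cell receptor genes, Xist and Y-linked genes were left out, as were genes under 10% of their CPM in the highest class in both libraries. T cells took the place of epithelial cells among the 3 main classes, because the latter had 77 cells in the motolimod library. Outside the rule, and chosen after their values were seen, are Tlr8, the background genes C1qa and S100a9, and the leading genes of clusters.

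Each of 24 gene lists fixed before the data were examined was compared in the classes it was written for. A member counted as measured with at least 20 UMIs over both libraries. The median log2 ratio of the measured members was given with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins, and members at least 1.5-fold higher or lower were counted. The list of 3 genes of the platelet factor 4 axis is included. A percentile describes these libraries only.

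The ratios, intervals and list percentiles were tested on simulated data drawn from the summed counts of all barcodes that passed the filter, motolimod over control, for 21141 genes. The 95% interval covered the true fold for 94% of 50 genes at a fold of 0.25, 94% at 0.5, 98% at 2 and 94% at 4. Counts were drawn as Poisson, which the interval assumes, so this checks the computation only. The simulated genes were taken above a count minimum at the depth of all cells. Genes of few UMIs and single classes are not covered. A simulated list of 20 genes at a fold of 2 reached percentile 100, and 11 of 200 unchanged lists fell outside percentiles 2.5 to 97.5.

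The analysis fixed 29 alternatives before the data were examined and added 16 afterwards. They vary the cell filter, the doublet treatment, the resolution, the genes used for clustering, the denominator, the scaling (median of ratios or trimmed mean of M values), the weight of each cell, the depth per cell and the low-count minimum. Epithelial, dendritic, NK, mast, fibroblast and endothelial cell-like cells had too few cells in a library for a comparison of genes.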

Results

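Single-cell RNA sequencing measured immune-enriched cells of mouse tumours in 2 groups, a control group and a group treated with motolimod, a small-molecule agonist of the endosomal RNA sensor TLR8. The labels name 5 mice per group and give 1 library per group. They do not state whether the mice were pooled. Nothing below has a replicate check, and every interval covers counting error only. The control library held 8099 barcodes and 127609378 UMIs, with a median of 12868 UMIs and 3091 genes per barcode. The motolimod library held 10037 barcodes and 62057685 UMIs, with a median of 3369 UMIs and 1285 genes. After filters, 6419 control and 8126 motolimod cells were kept.

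The first comparison asked which cell classes the tumours held with and without motolimod. Neutrophil-like cells, the short-lived granulocytes that arrive early in inflammation, made up 37.3% of kept cells in the motolimod library (3033 cells, interval 36.3 to 38.4) and 7.76% in the control library (498 cells, 7.12 to 8.44), a share 4.81-fold higher (4.37 to 5.30). Dendritic cell-like cells, which present antigen to T cells, were lower, at 1.05% (85 cells) against 5.11% (328 cells), a ratio of 0.205 (0.159 to 0.261). Epithelial cell-like cells, led by the keratins Krt8 and Krt18, made up 0.948% (77 cells) against 12.3% (787 cells), a ratio of 0.0773 (0.0603 to 0.0978). T cell-like cells made up similar shares, 4.42% (359 cells, 3.98 to 4.89) with motolimod and 4.89% (314 cells, 4.38 to 5.45) in the control, and their ratio of 0.903 had an interval from 0.774 to 1.05. That similarity depended on the doublet treatment, as given below.

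Monocyte/macrophage-like cells were the most frequent class in both libraries, at 50.3% in the control (3229 cells, 49.1 to 51.5) and 47.7% with motolimod (3877 cells, 46.6 to 48.8). NK cell-like cells, innate killer lymphocytes, were few, at 0.358% (23 cells) and 0.997% (81 cells), a ratio of 2.78 (1.73 to 4.63). Before T and NK cells were clustered again, the cluster named for NK cells held 93 control (1.45%) and 164 motolimod cells (2.02%). The size of the ratio therefore rests on the cells set aside. All 3 types of conventional dendritic cell-like cells were lower with motolimod. The cDC1-like cells, which cross-present antigen to CD8 T cells, numbered 82 and 22, with a ratio of shares of 0.212. The cDC2-like cells numbered 136 and 35 (ratio 0.203), and migratory dendritic cell-like cells, led by Ccr7 and Fscn1, numbered 110 and 28 (ratio 0.201). Mast cell-like cells numbered 29 and 8 (ratio 0.218), plasmacytoid dendritic cell-like cells 20 and 9 (ratio 0.356), fibroblast-like cells 14 and 16 (ratio 0.903) and endothelial cell-like cells 9 and 4.

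Some clusters scored highest for macrophage or monocyte markers but stayed unnamed, because markers of another class stood among their leading genes. Cluster 4, led by Mmp12, Mmp13, Ccl24 and Arg1, held 14.4% of control and 3.25% of motolimod cells. Cluster 19 held 0.685% and 1.16%, cluster 21 held 0.0623% and 0.541%, and cluster 23 held 0.530% and 0.0369%. With these added, monocyte/macrophage-like cells made up 65.9% and 52.7%. Cells set aside because genes of other myeloid cells led their subcluster made up 1.82% and 1.42% from the lymphocytes and 0.732% and 0.701% from the dendritic cells.

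Each library's shares also depend on the CD45 selection, on the depth gap between the libraries and on the denominator. Of named immune cells (4605 control and 7624 motolimod), neutrophil-like cells made up 10.8% and 39.8%, monocyte/macrophage-like cells 70.1% and 50.9%, and T cell-like cells 6.82% and 4.71%, a T cell ratio of 0.691 (0.592 to 0.806). Among immune cells other than neutrophil-like ones, T cell-like cells made up 7.65% and 7.82% and monocyte/macrophage-like cells 78.6% and 84.5%, which turned the direction for both classes, with ratios of 1.02 (0.877 to 1.19) and 1.07 (1.02 to 1.13). The T cell-like ratio over all kept cells also lay above 1 under the stricter cell filter (1.09) and with doublets removed by score alone (1.24). It was lower, at 0.760, with doublets kept and 0.700 with the removed T and macrophage droplets counted as T cells. That removal was unequal, at 423 of 812 control and 274 of 740 motolimod droplets with T cell core genes. Cluster 1 held 62.6% of the neutrophil-like cells with motolimod (1898 cells) and 8.03% in the control (40 cells). It was led by Lcn2, Serf1, Itpr2 and Ccl3, with no fixed neutrophil marker among its 10 leading genes, and a cluster mostly of 1 library may be that library and not a type. Without cluster 1, neutrophil-like cells made up 14.0% and 7.14% of kept cells, a ratio of 1.96 (1.75 to 2.19). Under the stricter filter of 1000 genes, 2000 UMIs and 5% mitochondrial UMIs, the dendritic cell-like ratio was 0.423 and the epithelial cell-like ratio 0.119.

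**Figure D1:**
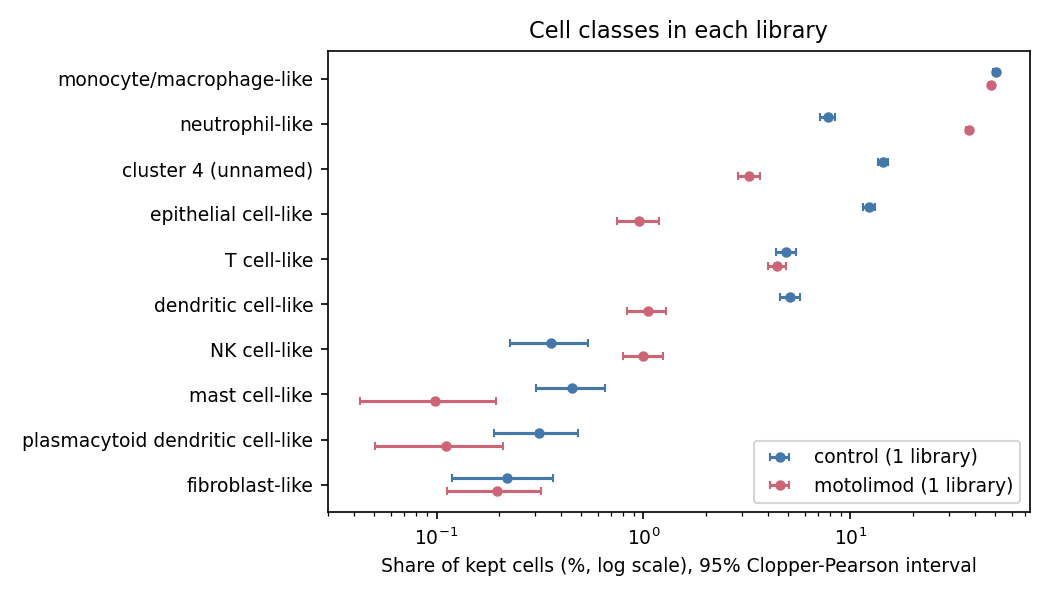
Share of kept cells (percent, log axis) in each cell class for the control and the motolimod library, 1 library each, with bars for the exact Clopper-Pearson 95% interval. Neutrophil-like cells lie at 7.76% in the control and 37.3% with motolimod, while the T cell-like points, at 4.89% and 4.42%, have overlapping intervals.

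The second comparison concerned Pf4 (ENSMUSG00000029373, chromosome 5, 90772435 to 90773383, plus strand, mm10), which encodes platelet factor 4, the chemokine named in the series title. Summed over monocyte/macrophage-like cells, Pf4 stood at 354 CPM (349 to 360) in the control and 2259 CPM (2242 to 2276) with motolimod, 6.38-fold higher (6.27 to 6.49). A Pf4 UMI was seen in 47.8% of these cells in the control and 68.9% with motolimod. Of all Pf4 UMIs in kept cells, monocyte/macrophage-like cells held 45.2% of 35079 in the control and 85.0% of 77386 with motolimod, and the unnamed clusters, mainly cluster 4, held 50.05% and 11.5%.

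Pf4 was higher with motolimod in each of the 7 monocyte/macrophage-like clusters, and in 14 of the 17 clusters of the class at a resolution of 2.0. The motolimod cells of this class were most frequent in cluster 0 (46.9%, against 4.49% in the control), while the control cells were most frequent in cluster 2 (31.7% against 12.7%) and cluster 3 (29.5% against 11.6%). Pf4 is itself among the genes that lead clusters 0 and 6, so the sizes of those clusters are no separate result. Within cluster 6, led by Gpnmb and Arg1, Pf4 stood at 542 and 5356 CPM (ratio 9.87, 9.27 to 10.5). Within cluster 0, led by Cbr2 and Tppp3, it stood at 1728 and 4220 CPM (2.44, 2.32 to 2.58), and within cluster 9, led by Cd209f and Lyve1, at 2111 and 4198 CPM (1.99, 1.91 to 2.08). The ratio was 21.2 (11.4 to 43.4) in cluster 15 (155 control and 85 motolimod cells), which had the classical monocyte genes Vcan and Ly6c2, from 9.72 CPM, the lowest control level of these clusters, to 206 CPM. The control level there lay between those of T cell-like and neutrophil-like cells. The ratio was 1.64 in cluster 2, 1.12 in cluster 3, 1.21 in cycling cluster 7 and 2.36 in unnamed cluster 4. After thinning, the share of cells with a Pf4 UMI was not higher in cluster 3 (8.31% and 7.87%) or cluster 7 (21.1% and 20.9%). With classes from a resolution of 2.0 the ratio over the class was 3.38, and with the unnamed clusters added it was 4.15. At the control library's mix of UMIs per cell it was 3.16 (3.10 to 3.21).

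After every cell was thinned to 1000 UMIs, which left out 31 control and 101 motolimod cells of the class, 19.6% and 51.1% of monocyte/macrophage-like cells held a Pf4 UMI. Median UMIs per cell of the class were 12504 and 5799. As background, dendritic cell-like cells held a Pf4 UMI in 4.57% and 14.1% of cells, and in 0.306% and 1.18% after thinning, with 1 and 0 cells left out and medians of 11416 and 11814 UMIs. T cell-like cells held a Pf4 UMI in 4.78% and 15.6%, and in 0.322% and 4.23% after thinning, with 3 and 4 cells left out and medians of 5114 and 4863 UMIs. Pf4 stood at 6.26 and 53.4 CPM in T cell-like cells, 6.91 and 36.5 CPM in dendritic cell-like cells and 27.0 and 62.4 CPM in neutrophil-like cells. These levels are read as background, which the removal of mixed droplets and of subclusters led by other lineages can lower. The levels lie below those of the whole macrophage class in the same library and, in the control, around that of cluster 15.

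Ppbp (ENSMUSG00000029372, chromosome 5, 90768518 to 90770063, plus strand), the neighbouring platelet chemokine gene, stood at 1.09 and 21.7 CPM in monocyte/macrophage-like cells (ratio 19.8, 14.8 to 27.1). Only 0.434% and 2.81% of the cells held a Ppbp UMI. Most of the motolimod UMIs came from cluster 6, at 10.5 and 107 CPM. Unnamed cluster 4 went the other way, at 21.8 and 15.2 CPM (0.699, 0.503 to 0.951), and with the unnamed clusters added the Ppbp ratio was 3.39 (2.98 to 3.85). The chemokine receptor gene Cxcr3 (ENSMUSG00000050232, chromosome X, 101731535 to 101734269, minus strand), which guides activated T cells, stood at 31.3 and 86.0 CPM in T cell-like cells, a ratio of 2.75 (2.12 to 3.59). With every T cell-like cell thinned to 1000 UMIs, the direction turned and the ratio was 0.844. A Cxcr3 UMI was seen in 18.5% and 25.3% of T cell-like cells, and in 7.72% and 6.20% after thinning. In monocyte/macrophage-like cells it was seen in 1.55% and 0.748%, and in 0.125% and 0.0794% after thinning. In NK cell-like cells, Cxcr3 stood at 62.4 and 63.1 CPM. Among the axis genes, the median log2 ratio in monocyte/macrophage-like cells, 2.67, is that of Pf4 itself. The medians of 0.83 in neutrophil-like and 2.28 in T cell-like cells rest on Cxcr3 and on Pf4 at background.

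**Figure D2:**
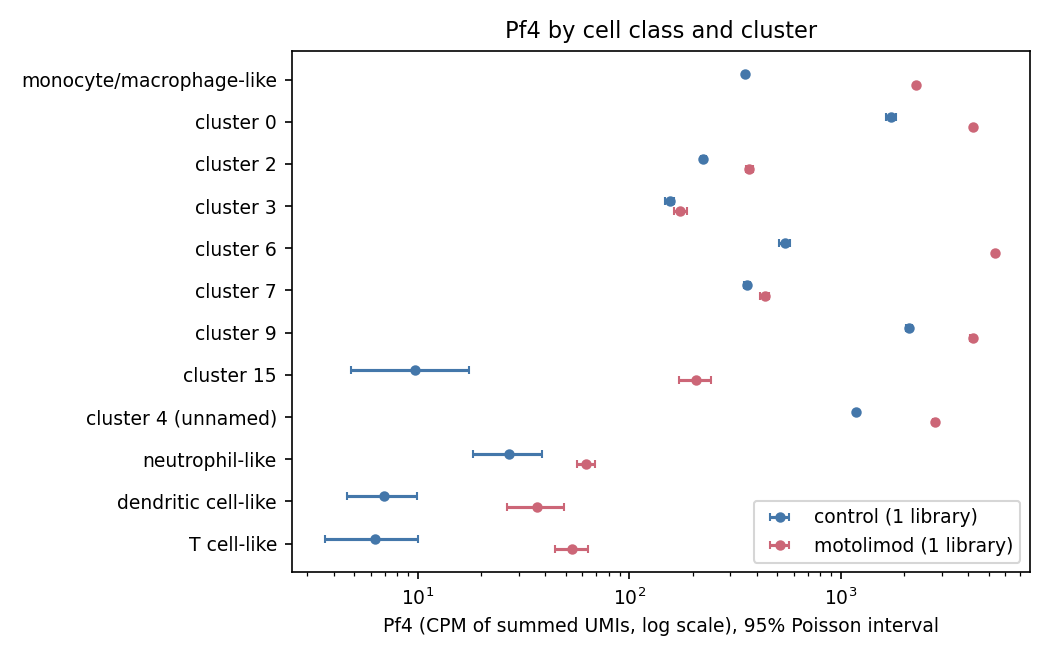
Pf4 in CPM of summed UMIs (log axis) by cell class and cluster for the control and the motolimod library, 1 library each, with bars for the exact Poisson 95% interval. Monocyte/macrophage-like cells lie at 354 and 2259 CPM, and T cell-like cells, shown as background, at 6.26 and 53.4 CPM.

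Summed over all monocyte/macrophage-like cells, most of the measured tissue-resident-like genes and 10 of 20 inflammatory NF-kB targets were at least 1.5-fold higher with motolimod, and most cell cycle genes were lower. The libraries differed in their mix of macrophage clusters, and many list medians differed in direction between clusters. Unnamed cluster 4 (922 control and 264 motolimod cells), which scored for this class, is left out of these sums. Its leading genes Arg1, Ccl24, Mgl2 and Fabp5 are members of the fixed lists, and no list median was computed with it added. Besides Pf4, the genes with the highest ratios were Gpnmb, a lysosomal glycoprotein gene of lipid-laden macrophages (7.49, 6.83 to 8.22), the fatty acid receptor gene Cd36 (7.25, 6.68 to 7.87), Tppp3 (4.49), the cholesterol exporter gene Abca1 (4.41), Sh3bp5 (3.55), the early response gene Egr1 (3.31) and the lectin receptor gene Clec4d (3.27). The lowest were the lectin gene Mgl2 (0.273, 0.253 to 0.295), the cell cycle genes Ube2c (0.356), Tk1 (0.373) and Tyms (0.381), Fdps of cholesterol synthesis (0.399), Srm of polyamine synthesis (0.419), the adhesion gene Vcam1 (0.426) and Cd81 (0.428). Of the genes above, Gpnmb, Cd36 and Tppp3 are among the genes that lead clusters 0 or 6. Vcam1 and Cd81 are among those of cluster 2 and Tk1 among those of cluster 7. Cluster 2 held 31.7% of control and 12.7% of motolimod cells of the class, and cluster 7 held 13.8% and 3.95%.

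Of 12 myeloid attracting chemokines, 7 were at least 1.5-fold higher and 2 lower in this class, with a median log2 ratio of 0.75 (percentile 100 of 10000 random lists matched on expression). By cluster, the median was 0.89 in cluster 6 and 0.25 in cluster 2, but −0.26 in cluster 0, −0.24 in cluster 3 and −0.85 in cluster 9. The neutrophil-attracting Cxcl2 stood at 859 and 2752 CPM (ratio 3.20), Cxcl3 had a ratio of 5.23, Cxcl1 of 3.12 and Cxcl5, at 0.0670 and 3.02 CPM, of 45.1 (14.9 to 223). Cxcl3 is not among the highest ratios above, so it fell under the minimum of 50 CPM or under 10% of its CPM in the highest class. No neutrophil background gene is given for this class. RNA of neutrophil-like cells, whose share was 4.81-fold higher with motolimod, is therefore not excluded for these genes. The 9 measured T cell attracting chemokines went both ways, 4 higher and 2 lower, with a median of 0.01 (percentile 64.8) that turned to −0.04 under median-of-ratios scaling, and by cluster 0.54 in cluster 2, 0.64 in cluster 3 and −0.63 in cluster 9. Ccl5, which attracts T cells, had a ratio of 2.75, while Ccl22 (0.308) and Ccl17 (0.345) were near the detection floor, and Ccl17 turned to 1.28 with doublets kept. Inflammatory NF-kB targets were 10 higher and 0 lower of 20 (median 0.57, percentile 100), among them the nitric oxide synthase gene Nos2 (3.86), Il10 (2.95), Tnfaip3 (2.32), Il23a (2.62, at 1.58 CPM) and Tnf (2.21). Their median was 0.61 in cluster 3, 0.33 in cluster 2 and 0.37 in cluster 7, but −0.39 in cluster 0 (0 higher and 7 lower), −0.10 in cluster 6 and −0.76 in cluster 9. The Toll-like receptor pathway had 6 higher and 0 lower of 16 (0.37, percentile 99.6). The RNA sensor gene Tlr7 was at 17.7 and 36.7 CPM (2.08, 1.89 to 2.28) and Tlr8 at 8.06 and 10.1 CPM (1.25, 1.07 to 1.46), with Tlr3 at a ratio of 1.81 and Tlr4 at 1.65. By cluster, the Tlr7 ratio was 3.73 in cluster 6, 1.75 in cluster 9 and 1.38 in cluster 0, but 1.08 in cluster 3 and 0.822 in cluster 7. The Tlr8 ratio was 1.44 in cluster 2 and 1.68 in cluster 6, but 0.941 in cluster 0, 0.918 in cluster 7 and 0.805 in cluster 9, and a Tlr8 UMI was seen in 9.85% of control and 6.35% of motolimod cells of the class (0.719% and 1.03% after thinning). The pathway median was 0.37 in cluster 6, while that of −0.02 in cluster 0 turned to 0.01 under median-of-ratios scaling.

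Type I interferon response genes, the antiviral programme, were 8 higher and 0 lower of 22 in monocyte/macrophage-like cells (median 0.38, percentile 99.99), with Ifi44 at 2.76, Ddx60 at 2.34, Oas3 at 2.03 and Oas2 at 1.97. The direction was not shared by the clusters of the class. The median was 1.03 in cluster 6 and 0.33 in cluster 0, but −0.58 in cluster 2, −0.66 in cluster 7, −0.22 in cluster 3 and −0.28 in cluster 9, and −0.35 in unnamed cluster 4. Interferon-gamma response genes had 1 higher (Irgm2, 1.70) and 1 lower (Serpina3g, 0.544) of 21, with a median of 0.18 (percentile 96.3) that turned to −0.18 as a mean over cells and to −0.13 after thinning. It was 0.47 in cluster 2, 0.56 in cluster 3 and 0.64 in clusters 6 and 7, but −0.19 in cluster 0 and −0.40 in cluster 9. MHC class I genes were within 1.5-fold in all 13 cases (−0.04, percentile 61.0), with H2-Q7 at 1.34 and Psmb8 at 0.704.

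MHC class II genes, which present antigen to CD4 T cells, had 0 higher and 3 lower of 9 (median −0.50, percentile 0.06), with H2-DMb2 at 0.459, H2-DMb1 at 0.615 and H2-Eb1 at 3201 and 2201 CPM (0.688). By cluster, their median was −1.69 in cluster 0, −1.92 in cluster 6 and −1.11 in cluster 9, but −0.03 in cluster 3, 0.38 in cluster 7 and 0.01 in cluster 2, where it turned to −0.08 under median-of-ratios scaling. Tissue-resident-like macrophage genes had 8 higher and 3 lower of 11 (0.79, percentile 100), with the growth factor gene Igf1 at 4.82, Selenop at 2.71, Cbr2 at 2.51 and Lyve1 at 0.351. Their median was 1.42 in cluster 6, but −0.16 in cluster 0 and −0.13 in cluster 9. Lipid and lysosome genes had 4 higher and 0 lower of 15 (0.37, percentile 99.9), among them Apoc2 (2.18) and the protease gene Ctsd (2.13) beside Gpnmb and Cd36. Their median was 0.86 in cluster 6 and 0.11 in cluster 0, but −0.10 in cluster 2, −0.08 in cluster 3 and −0.26 in cluster 7. Classical activation genes had 2 higher, Nos2 and Tnf, and 0 lower of 12 (−0.15, percentile 21.9), with medians from −0.72 in cluster 9 to 0.23 in cluster 7. Alternative activation genes had 4 higher and 4 lower of 14 (0.15, percentile 89.1), with Stab1 at 2.21 and Mgl2 lowest, and the median turned to −0.35 as a mean over cells and to −0.15 after thinning. By cluster it ranged from −0.67 in cluster 6 to 0.41 in cluster 3.

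Proliferation genes had 0 higher and 13 lower of 14 in monocyte/macrophage-like cells, with a median of −1.13 (percentile 0), among them Ccnb2 (0.397) and Ccnb1 (0.425). Within cluster 7, whose leading genes are cell cycle genes, the median was −0.06. It was 0.21 in cluster 3, −0.31 in cluster 2, −0.69 in cluster 6, −1.44 in cluster 0 and −3.17 in cluster 9. Hypoxia and glycolysis genes had 0 higher and 2 lower of 14 (−0.15, percentile 16.5), with the lactate dehydrogenase gene Ldha at 0.659. Their median was −0.99 in cluster 6 (0 higher and 13 lower), −0.98 in cluster 9, −0.37 in cluster 0 and −0.16 in cluster 7, but 0.25 in cluster 3, and 0.06 in cluster 2 turned to −0.03 under median-of-ratios scaling. Stress genes that tissue dissociation can raise had 4 higher and 1 lower of 15 (0.19, percentile 97.8), with Egr1 at 3.31, Fosb at 2.47, Atf3 at 1.64 and Hspa1b at 0.594. By cluster, the stress median was −0.16 in clusters 2 and 7, −0.26 in cluster 3 and −0.39 in cluster 6, against 0.04 in cluster 0 and 0.07 in cluster 9.

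The clusters of this class differed in their largest ratios. In cluster 6 the interferon gene Ifi44 (17.4), the acute phase gene Saa3 (12.97) and Ppbp (10.2) were highest, and Retnla (0.0139), Ccl24 (0.0423) and the decoy receptor gene Il1r2 (0.0728) were lowest. In cluster 0 Gpnmb (57.1, from 1 control UMI, 10.2 to 2258) and Cd36 (5.09) were highest with the immunoglobulin gene Ighg2b, which was at 0 UMIs in the control and higher by a log2 ratio of at least 4.76 against a floor of 3 counts. Lowest there were the class II genes H2-Eb1 (0.210) and H2-Ab1 (0.229) and Retnla (0.214). In cluster 9 Cd36 (10.4), the lipase gene Lpl (3.20) and Adgre5 (3.06) were highest, and Lrg1 (0.0257), Cd72 (0.0680) and the lectin gene Cd209b (0.0970) lowest. Tnf was among the highest in cluster 2 (2.97) and cluster 7 (2.18), with the metabolic gene Arg1 (2.51) and Tnfaip2 (2.42) in cluster 2 and Lars2 (2.39) and the interferon-gamma target Gbp2b (2.18) in cluster 7. In cluster 3 Nos2 (5.07), Ifitm1 (3.73) and the activin gene Inhba (3.61) were highest. The eosinophil-attracting chemokine gene Ccl24 was lowest in clusters 2 (0.0658), 4 (0.263) and 7 (0.108). The heat-shock gene Hspa1b was among the lowest in clusters 2 (0.342), 3 (0.274) and 7 (0.182), with Isg15 (0.342) in cluster 2, Gdf3 (0.215) and Siglec1 (0.375) in cluster 3 and Gdf15 (0.294) in cluster 7. In unnamed cluster 4, Maf (2.22) and B4galt6 (2.17) followed Pf4, and Spp1 (0.387) and Fcna (0.388) followed Ccl24.

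Summed over all neutrophil-like cells, most MHC class I, interferon-gamma response and granule genes were at least 1.5-fold higher with motolimod, and most stress genes were lower. The highest ratios were those of Serf1 (53.7, 20.9 to 197), the granule peptide gene Camp (34.4, 9.48 to 285), the granulocyte growth factor gene Csf3 (21.4, 8.30 to 78.7), the antioxidant gene Srxn1 (14.0), the kinase gene Ikbke (12.7), Creg1 (11.9, 9.38 to 15.2), Acot1 (10.7) and the iron transporter gene Slc25a37 (8.54). The lowest were Igfbp6 (0.173, 0.155 to 0.193), Lrg1 (0.227), Bin2 (0.229), AW011738 (0.231), the clock-related gene Ciart (0.237), Ifitm1 (0.252), AB124611 (0.259) and Tnfaip6 (0.281). Cluster 1 held most of the motolimod cells, 62.6%, while cluster 5, led by Retnlg and G0s2, held most of the control cells, 58.0% against 23.6%, and cluster 8, led by Ngp and Lrg1, 33.9% against 13.8%. Serf1, Lcn2 and Ccl3 are among the genes that lead cluster 1, so their ratios and its size are not separate results. Other scalings moved all log2 ratios of this class by −0.20 or −0.19. The lists were compared within clusters 5 and 8, but not within cluster 1, which had 40 control cells.

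MHC class I presentation genes had 10 higher and 0 lower of 13 in neutrophil-like cells (median 0.99, percentile 100), with H2-Q7 at 4.52, the peptide transporter gene Tap2 at 3.50, Psme2 at 3.14 and Psmb10 at 2.69. Their median was 0.43 within cluster 5 (5 higher) and 0.65 within cluster 8 (7 higher). Under median-of-ratios scaling it was 0.79 in the class, 0.79 in cluster 5 and 0.42 in cluster 8, so only the cluster 8 value stayed below that of the class. Interferon-gamma response genes had 11 higher and 2 lower of 18 (0.75, percentile 99.8), with Tgtp2 at 8.96, Gbp6 at 8.71, from 2 control UMIs, Gbp4 at 7.40 and Iigp1 at 0.190, and a median of 0.72 within cluster 5 and 0.62 within cluster 8. Immature granule genes had 5 higher and 2 lower of 8 (1.53, percentile 100), with the iron-binding Lcn2 at 708 and 2915 CPM (4.12), the collagenase gene Mmp8 at 3.11 and Ngp at 4.15. After thinning, this median was 0.59 and the Ngp ratio 1.14. Within cluster 5 it was 0.37 (1 higher of 4 measured genes), and within cluster 8, led by Ngp itself, 1.82 (6 of 7). Mature neutrophil genes had 1 higher (Slpi, 1.71) and 4 lower of 10 (−0.52, percentile 1.97), with Retnlg at 0.356 and the chemokine receptor gene Cxcr2 at 0.598, and their median was 0.13 within cluster 5 and −0.26 within cluster 8. Inflammatory NF-kB targets had 8 higher and 1 lower of 17 (0.27, percentile 92.6), with Tnf at 4.64, Sod2 at 4.62, Icam1 at 3.05 and Cd40 at 0.164, and a median of 0.36 within cluster 5 and 0.34 within cluster 8.

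The 7 measured T cell attracting chemokines had 3 higher and 2 lower in neutrophil-like cells (0.41, percentile 78.8). Ccl3 stood at 4792 and 11147 CPM (2.33) and Ccl4 at 7625 and 15323 CPM (2.01), while Ccl5 had a ratio of 0.232. The median was 1.02 as a mean over cells, and 0.43 within cluster 5 and 1.54 within cluster 8. Myeloid attracting chemokines had 2 higher and 4 lower of 9 (0.11, percentile 49.3), with Cxcl1 at 3.07, Ccl8 at 0.393, Ccl6 at 0.481 and Ccl12 at 0.493, which turned to 1.07 after thinning. Their median turned to −0.09 under median-of-ratios scaling. It was −0.38 within cluster 5 and 0.30 within cluster 8, but 0.01 and 0.05 under trimmed-mean scaling. Type I interferon genes were at a median of 0.06 (percentile 40.5), 6 higher and 2 lower of 21, with Stat2 at 1.89 and Bst2 at 1.71, and the median turned to −0.14 under median-of-ratios scaling. Within cluster 5 it was 0.84 (percentile 100), with 15 higher and 0 lower, and within cluster 8 it was 0.34. Toll-like receptor pathway genes had 3 higher and 0 lower of 14 (0.33, percentile 43.2), with Irak1 at 2.38 and Tlr2 at 1.66, and the median turned to −0.14 after thinning. Tumour-associated neutrophil genes had 3 higher and 2 lower of 12 (−0.22, percentile 16.5), with Xbp1 at 0.320, Siglecf at 0.411 and Olr1 at 2.08, and their median was 0.76 within cluster 8 and −0.09 within cluster 5, where it turned to 0.26 under median-of-ratios scaling. Hypoxia genes had 1 higher and 2 lower of 14 (−0.20, percentile 18.6), with the glucose transporter gene Slc2a1 at 0.426, and their median was −0.58 within cluster 5 and 0.53 within cluster 8.

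Stress genes had 0 higher and 10 lower of 15 in neutrophil-like cells (−0.68, percentile 0.06), with Hspa1b at 0.370, Hspa1a at 0.375, Dnajb1 at 0.430 and Fos at 0.444, and their median was −0.72 within cluster 5 and 0.15 within cluster 8, where it turned to −0.09 under median-of-ratios scaling. The macrophage gene C1qa, a marker of other cells' RNA, stood at 27.0 and 25.3 CPM in this class. Its level can be lowered by the removal of droplets with macrophage and neutrophil core genes. Within cluster 5, Csf3 (26.9, 9.04 to 131), Gsap (5.03) and Lcn2 (4.95) were highest and Gdf15 (0.111), Ciart (0.227) and Igfbp6 (0.231) lowest, on a scale that other scalings shifted by 0.36 or 0.39. Within cluster 8, Ngp (35.5, 16.2 to 97.2) and H2-Q6 (16.5) were highest beside Camp, at 0 UMIs in the control and higher by a log2 ratio of at least 4.77 against the same floor, and Plaur (0.304), Wfdc17 (0.316) and Retnlg (0.321) were lowest, with shifts of −0.24 or −0.25.

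The third comparison, of T and NK cells, bears on the T cell recruitment in the series title. Among T and NK cell-like cells (337 control and 440 motolimod), NK cell-like cells made up 18.4% with motolimod (81 cells) and 6.82% in the control (23 cells), a ratio of 2.70 (1.68 to 4.49). This ratio also rests on the cells set aside, since the NK cluster first held 164 motolimod and 93 control cells. Regulatory T cell-like cells, which restrain immune responses, made up 2.73% (12 cells) against 11.3% (38 cells), a ratio of 0.242 (0.115 to 0.473). CD8 T cell-like cells, the cytotoxic T cells, made up 36.8% (162 cells) against 45.7% (154 cells), and their ratio of 0.806 had an interval from 0.642 to 1.01 and was 1.05 with doublets removed by score alone. They formed 2 subclusters. The one led by the cell cycle genes Ube2c, Birc5 and Mki67 held 59 control and 35 motolimod cells (0.454, 0.290 to 0.702), while the other held 95 and 127, a ratio of 1.02 (0.779 to 1.35). Gamma-delta T cell-like cells, with Il17a among their leading genes, made up 17.0% against 23.7% (0.718, 0.517 to 0.997). The remaining T cells lay in an unnamed subcluster led by Gramd3, Cxcr3, Cd4 and Ly6c2, which held 110 motolimod and 42 control cells, a ratio of 2.01 (1.39 to 2.93). It scored highest for CD8 T cells (6.28, against 5.35 for CD4 T cells). The lower CD8 T cell-like share therefore depends on leaving it out, and the share with it added was not computed.

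Within T cell-like cells, most type I interferon response genes were at least 1.5-fold higher with motolimod, and most regulatory T cell programme and proliferation genes were lower. The highest ratios were those of Rasgrp2 (3.22, 2.37 to 4.42), the early response gene Fosb (2.93), Ccl5 (2728 and 7976 CPM, 2.92), the T cell receptor gene Trbc1 (2.85), Ly6c2 of effector and memory CD8 T cells (2.75), Cxcr3 (2.75), Ifi209 (2.58) and the chromatin organiser gene Satb1 (2.54). The lowest were the granzyme genes Gzmg (0.0769, 0.0456 to 0.122) and Gzmc (0.2504), Ccdc184 (0.199), the regulatory T cell receptor gene Ccr8 (0.223), Penk (0.259), Slc16a11 (0.264), Dusp14 (0.281) and the lymph node homing receptor gene Ccr7 (0.287). Cxcr3 and Ly6c2 are among the genes that lead the unnamed T cell subcluster of 42 control and 110 motolimod cells, so their ratios and its size are not separate results. After thinning, the ratio of Rasgrp2 was 1.36, of Fosb 1.52 and of Trbc1 1.64. Other scalings moved all log2 ratios of this class by −0.12 or −0.10.

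Type I interferon response genes had 15 higher and 1 lower of 19 in T cell-like cells (median 0.71, percentile 100), with Ifit3 at 4.78, Usp18 at 4.44, Ifi204 at 3.18 and Ifit1 at 3.02. After thinning, the median was 0.27. Interferon-gamma response genes had 7 higher and 2 lower of 18 (0.44, percentile 99.97), with Tgtp2 at 2.46, Irgm1 at 1.96, Gbp2 at 1.93 and Gbp4 at 1.88. Homing and adhesion receptors had 7 higher and 1 lower of 14 (0.64, percentile 100), with the tissue-residence integrin gene Itga1 at 3.23 and Ccr2 at 2.39, and Ccr8 as the lower gene. Naive and memory genes had 5 higher and 1 lower of 8 (0.90, percentile 100), with the trafficking regulator gene Klf2 at 2.20 and Lef1 at 2.19, but their median was −0.16 as a mean over cells and 0.15 after thinning. The 6 measured T cell attracting chemokines had 3 higher and 1 lower (0.31, percentile 94.3), Pf4 at background among them, with Ccl4 at 1.56 and Cxcl16 at 0.378 (0.108 to 1.08).

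Cytotoxic effector genes had 1 higher, Gzma (3.81, 3.43 to 4.24), and 1 lower, Gzmc, of 15 in T cell-like cells, with a median of 0.33 (percentile 99.6) and Gzmk and Klrd1 both at 1.48. Gzma is not among the highest ratios above, which leave out genes under 10% of their CPM in the highest class. It is among the leading genes of the NK cell-like subcluster (23 control and 81 motolimod cells), so RNA of NK cells is not excluded for it. Exhaustion genes had 1 higher (Cd160, 1.55) and 1 lower (Tnfrsf9, 0.483) of 12 (−0.12, percentile 17.8), with Rgs16 at 0.707 and Tox at 0.737. The regulatory T cell programme had 1 higher and 7 lower of 9 (−0.92, percentile 0), with its master regulator gene Foxp3 at 0.370 and Tnfrsf4 at 0.338, beside the lower share of regulatory T cell-like cells. Within CD8 T cell-like cells alone the programme was lower too, with 1 higher and 5 lower of 8 (−0.83, percentile 0) and Foxp3 at 0.343, Tnfrsf4 at 0.363 and Ccr8 at 0.399. These cells include the cycling subcluster (59 control and 35 motolimod cells), which had no CD8 marker among its 10 leading genes. Regulatory T cells within it are not excluded, so this is not a result separate from the mix. Proliferation genes had 0 higher and 8 lower of 14 (−0.69, percentile 0), with Ccnb1 at 0.377 and Ube2c at 0.397. Hypoxia and glycolysis genes had 0 higher and 4 lower of 13 (−0.37, percentile 0.16), with Ndrg1 at 0.535, Mif at 0.562 and Ldha at 0.586. MHC class I genes were within 1.5-fold in all 13 cases (0.09, percentile 81.5), and this median turned to −0.04 under median-of-ratios scaling. Stress genes had 3 higher and 2 lower of 15 (0.07, percentile 69.2), turning to −0.05 under the same scaling. The neutrophil gene S100a9 stood at 3.68 and 22.3 CPM in T cell-like cells and the macrophage gene C1qa at 14.0 and 18.3 CPM, as measures of other cells' RNA. Both can be lowered by the removal of droplets with core genes of several lineages.

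CD8 T cell-like cells had median UMIs of 11478 and 6701, and 59 of 154 control and 35 of 162 motolimod cells lay in the cycling subcluster, so the values that follow compare different mixes. In these cells alone, homing receptors had a median of 0.94 (percentile 100), interferon-gamma response genes 0.60 (100), type I interferon genes 0.68 (99.96), cytotoxic genes 0.36 (99.8) and exhaustion genes 0.19 (93.6). T cell attracting chemokines had a median of 1.00, naive and memory genes 0.83, stress genes 0.31 (percentile 99.1), MHC class I genes 0.06 (−0.04 under median-of-ratios scaling), proliferation genes −0.36 and hypoxia genes −0.52 (percentile 0.01). Fosb (3.89), Trbc1 (3.62) and Klf2 (3.56) had the highest ratios there, and Gzmg (0.10025), the heat-shock gene Hspa1a (0.197) and the immunoglobulin gene Igkc (0.213) the lowest.

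**Figure D3:**
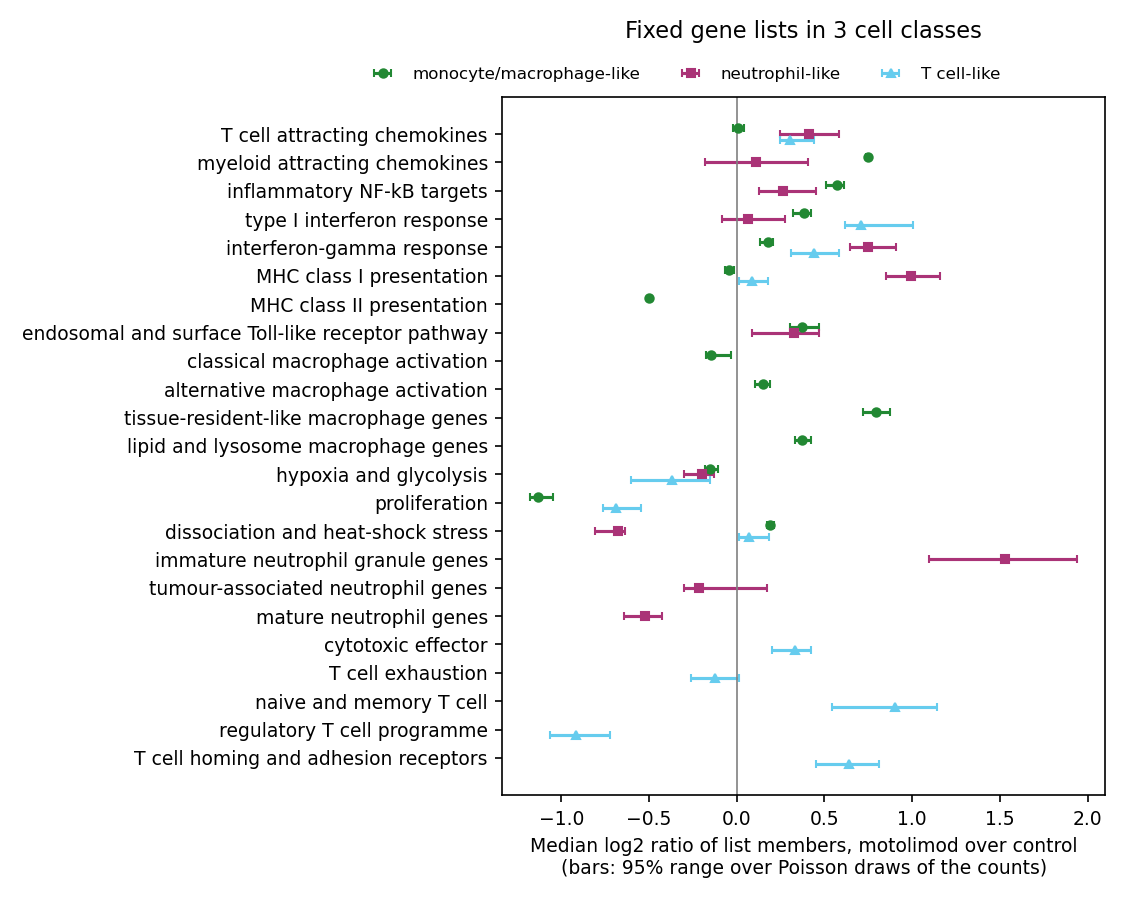
Median log2 ratio, motolimod over control, of the measured members of each fixed gene list, except the platelet factor 4 axis, in monocyte/macrophage-like, neutrophil-like and T cell-like cells, with bars for the 95% range over Poisson draws of the counts and 1 library per group. Proliferation genes in monocyte/macrophage-like cells lie lowest, at −1.13, and immature granule genes in neutrophil-like cells highest, at 1.53; the T cell-like MHC class I and stress medians of 0.09 and 0.07 turned to −0.04 and −0.05 under median-of-ratios scaling.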

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

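The tests of Pf4 at a fixed mix of clusters or of UMIs per cell, of free RNA and of other non-immune cells were chosen only after the results they examine had been seen, as were the bounds that each test was read against.

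Droplets with both macrophage and neutrophil core genes, which no comparison of the report uses, made up 5.55% of passing motolimod barcodes (517 droplets, interval 5.09 to 6.04) and 3.19% of control barcodes (239 droplets, 2.81 to 3.62). Independent pairing of the core genes would give 1477 and 495. That number takes every droplet as able to carry both lineages, so it is no expected number of doublets. Neutrophil core genes were held by 3472 motolimod and 832 control droplets, so the higher share is not read as more pairing. Stress and heat-shock genes had a median log2 ratio of 0.19 in monocyte/macrophage-like cells and of −0.68 in neutrophil-like cells, and the difference between the classes was not tested. By cluster, 4 of the 6 compared macrophage clusters lay below 0 (−0.16, −0.26, −0.39 and −0.16 in clusters 2, 3, 6 and 7), so the direction of the macrophage class was not shared by all of its clusters.

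Pf4 was 6.38-fold higher in monocyte/macrophage-like cells of the motolimod library. At the control library's mix of UMIs per cell, over 10 bins, the ratio was 3.16 (3.10 to 3.21), and Pf4 was higher with motolimod in all 10 bins, which argues against the difference in UMIs per cell as the whole cause, while that difference alone gave 1.38. Median UMIs of control and motolimod cells were 12504 and 5799 in the class, but closer within clusters, such as 4256 and 3969 in cluster 0 and 16514 and 14809.5 in cluster 2. The bins thus also held part of the cluster mix fixed and are no separate test of library depth. At the control library's mix of clusters the ratio was 2.19 (2.14 to 2.23), and 1.63 (1.59 to 1.67) with the finer clusters of resolution 2.0, while the mix alone gave 2.20 and 2.76. The ratio left was smaller with finer clusters, and a different mix inside a cluster is not held fixed. The mix as the whole cause therefore stays open. Unnamed clusters are left out of these ratios. Pf4 gained by T cell-like cells, meant as a measure of free RNA, came to 2.48% of the gain in monocyte/macrophage-like cells (47.2 against 1905 CPM). Mixed T and macrophage droplets had been removed, and lymphocyte subclusters led by genes of other lineages set aside. The set-aside cells held 921 control and 1624 motolimod Pf4 UMIs, against 17 and 120 in T cell-like cells. A low gain was thus partly fixed by the filters, and free RNA is not excluded by it. A different mix of macrophages, with or without a higher Pf4 level within them after motolimod, is a candidate explanation, and a difference between the libraries other than treatment stays open.

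Neutrophil-like cells made up a 4.81-fold larger share of the motolimod library. Under the stricter cell filter the ratio was 6.15, which argues against more barcodes of few UMIs as the cause. Shares are relative, so they do not show whether neutrophil-like cells were more or the other classes fewer. With 1 library per group, an effect of motolimod and a difference between libraries other than treatment cannot be told apart. The size also rests on cluster 1, without which the ratio of shares was 1.96.

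Epithelial cell-like cells made up a smaller share of the motolimod library, with a ratio of 0.0773. In the control library they made up 12.3% of kept cells, more than the stated purity of above 95% leaves room for. A weaker CD45 selection in the control library would let in other non-immune cells too. Their ratio was 0.687 (0.358 to 1.31), from 23 control and 20 motolimod cells, which argues against selection as the whole cause. The fibroblast-like ratio was 0.903 (0.413 to 2.00), and the endothelial cell-like ratio of 0.351 (0.0790 to 1.26) excludes nothing on its own. With doublets kept the epithelial ratio was 0.0803, which argues against the removal of doublets as the cause. Fewer tumour cells per immune cell after motolimod, or epithelial cells that passed the selection unequally, may account for it, and neither was tested.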

How the results depend on the processing

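Chosen after seeing the data were doublets by score or by mixed lineage alone, immune cells without neutrophils as denominator, unnamed clusters added (for Ppbp too), clusters without a leading marker left out, T and macrophage droplets counted as T cells, the scalings of Pf4, and the filters and doublet rules for the T and NK subclasses. The others were chosen before. No paired analysis was possible because each group has 1 library. Of 1132 ratios of named genes under alternatives, 795 lay within the main counting interval, 1022 lay within 1.5-fold of the main value and 6 reversed. Only results whose main interval excluded no difference are counted as reversed. Of all results, 8 gene ratios, 22 list medians and 5 share ratios lay on the other side of no difference from their main value. Of 195 list medians 99 lay within the main interval, 82 moved and 14 reversed. Of 105 share ratios 76 stayed within it, 28 moved and 1 reversed. The shares of the 4 T and NK subclasses were run with subclusters at resolutions 0.5 and 2.0, thinned, and with the other cell filters and doublet rules. They stayed within it, except for the CD8 T cell-like ratio (0.806), which was 1.05 with doublets by score alone. The dendritic cell-like ratio ranged from 0.125 to 0.423, the NK cell-like ratio from 2.04 to 4.34 and the epithelial cell-like ratio from 0.0735 to 0.119. With the minimum lowered to 10 CPM and 30 UMIs, 5, 4 and 1 of the 16 highest and lowest genes remained in monocyte/macrophage-like, neutrophil-like and T cell-like cells. Ppbp in T cell-like cells gave no finite ratio. Below, the cause was not tested for any value.

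The neutrophil-like share ratio (4.81) was 6.15 under the stricter filter of 1000 genes, 2000 UMIs and 5% mitochondrial UMIs, 3.68 over immune cells and 1.96 without clusters that lack a marker among their leading genes. The monocyte/macrophage-like share ratio (0.948) was 0.852 under the looser filter, 0.828 and 0.788 at resolutions 0.5 and 2.0, 0.866 without response genes, 0.692 with each library clustered on its own, 0.827 thinned, 0.880 and 0.837 with doublets by score or by mixed lineage alone, 0.725 over immune cells and 0.799 with unnamed clusters added. It reversed to 1.07 over immune cells without neutrophils. The T cell-like share ratio (0.903) was 1.09 under the stricter filter, 0.760 with doublets kept, 1.24 with doublets by score alone, 0.691 over immune cells, 1.02 over immune cells without neutrophils and 0.700 with T and macrophage droplets counted as T cells. The Pf4 ratio in monocyte/macrophage-like cells (6.38) was 6.16 and 6.18 under median-of-ratios and trimmed-mean scaling, 7.40 as a mean over cells, 7.62 thinned, 4.97 with doublets kept, 5.54 and 5.11 with doublets by score or by mixed lineage alone, 5.24 and 3.38 at resolutions 0.5 and 2.0, 4.89 without response genes, 4.15 with unnamed clusters added and 8.05 without clusters that lack a marker among their leading genes.

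The type I interferon median in monocyte/macrophage-like cells (0.38) was 0.49 as a mean over cells and 0.46 thinned. In neutrophil-like cells (0.06) it was −0.14 and −0.13 under median-of-ratios and trimmed-mean scaling and 0.30 thinned. In T cell-like cells (0.71) it was 0.58 under median-of-ratios scaling, 0.56 as a mean over cells and 0.27 thinned. As a mean over cells, reversals were −0.18 for interferon-gamma response and −0.35 for alternative activation in monocyte/macrophage-like cells, and in T cell-like cells −0.0571 for MHC class I, −0.16 for naive and memory genes, −0.18 for stress genes and a ratio of 0.967 for H2-D1. Thinned, they were −0.13 and −0.15 for the same pair of macrophage lists, −0.14 for the Toll-like receptor pathway and 1.07 for Ccl12 in neutrophil-like cells, and in T cell-like cells −0.12 for MHC class I, −0.15 for stress genes, 0.844 for Cxcr3, 0.9502 for H2-D1 and 0.904 for Tapbp. Under median-of-ratios and trimmed-mean scaling, MHC class I in T cell-like cells was −0.0380 and −0.00887 and stress genes −0.0531 and −0.0239. Over all classes and clusters, 21 of 193 list medians lay on the other side of no difference under at least 1 of these scalings. With doublets kept, Ccl17 in monocyte/macrophage-like cells was 1.28.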

Other observations

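No test in this part was run beyond the values given.

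Some small clusters had leading genes known from cell types outside the comparisons. Cluster 23, with 34 control and 3 motolimod cells, was led by Ctsk, Acp5, Dcstamp and Ocstamp, which are known from osteoclasts and other fused bone-resorbing cells. Mast cell-like cells, led by the protease genes Mcpt4, Cma1 and Tpsb2, numbered 29 and 8. Cluster 19, with 44 and 94 cells and medians of 1444.5 and 1247.5 UMIs, was led by the antibody genes Jchain, Igkc and Ighm. It scored 3.86 for monocytes or macrophages and 2.16 for plasma cells. Jchain and Igkc were also among the leading genes of the NK cell-like subcluster and of a dendritic cell-like cluster. RNA of other cells was therefore not excluded, here or for the immunoglobulin genes named in cluster 0 and CD8 T cell-like cells. No cluster took the name of B cells, plasma cells, basophils, eosinophils or platelets.

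Droplets with T cell and macrophage core genes together, which were removed as mixed, numbered 423 in the control (5.65% of passing barcodes, interval 5.14 to 6.20) and 274 with motolimod (2.94%, 2.61 to 3.31). Independent pairing of the core genes would give 483 and 315. That number takes every droplet as able to carry both lineages, so it is no expected number of doublets and no conclusion is drawn from it. Droplets with macrophage and epithelial genes numbered 137 (1.83%) and 8 (0.0859%). Independent pairing would give 548 and 38.3, with the same limit.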
